A study of Homo sapiens with 8 samples.

How the data were processed

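Gene-level RNA-seq of human CD8+ T cells was analysed from 2 tables that the authors deposited, one of counts and one of FPKM, each with 8 samples in 4 groups of 2 (PBS, WT IL-10, super-10 and 10-DE). Per the labels' protocols, CD8+ T cells were isolated from blood mononuclear cells with magnetic beads, activated for 3 days with anti-CD3 and anti-CD28 and treated for 24 h, RNA was purified on columns, and libraries were made from mRNA with a NEBNext Ultra II kit. The protocol text gives 10 nM IL-10 for all samples alike, and the PBS samples were taken as untreated from their own labels. The deposited counts are whole numbers of reads per gene and were not normalised. The submitters' processing notes name STAR 2.5 and the builds GRCh38 and hg38, and the tool that counted reads, its strand setting and the annotation are not given in the sources used here. Gene starts and ends in the table equalled those of GENCODE 29 for 58724 of 58735 genes, so positions are on GRCh38. The deposited FPKM values had the same zeros as the counts, with 0 exceptions, and were the count divided by the sample total and by a length per gene: among 23583 genes with a value in at least 2 samples, this implied length varied by under 1% for 100% of them. No column of the tables fell outside these samples.

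Each column was assigned to its sample by name, and samples to groups by the labels. Counts were filtered with filterByExpr by group, leaving 14058 of 58735 genes, scaled by TMM factors (0.983 to 1.01) and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust off, glmQLFTest, two-sided, Benjamini-Hochberg over all genes tested, adjusted p under 0.05, no minimum fold). All 8 samples entered a single fit with 4 residual degrees of freedom, since 2 samples per group give little information on the spread alone; the common biological coefficient of variation was 5.12%. The 6 pairwise comparisons were made. The standard error of a log2 change is its size divided by the square root of the F statistic, and intervals are 1.96 standard errors on each side. The tests, the alternatives, the 19 pathway and 8 cell type lists (468 genes) and the rule for named genes were fixed before the data were examined. That rule names, per comparison, the 10 largest rises and the 10 largest falls among called protein-coding genes whose samples did not overlap between groups and whose higher mean was at least 2 CPM, the 10 called list members with the smallest adjusted p, and IL10, IL10RA, IL10RB, SOCS3, IFNG, GZMB and PRF1 always; up to 10 members may be named beside a list's count. Genes with only an identifier or no protein product, T cell receptor and immunoglobulin segments, HLA and KIR genes, Y-linked genes and XIST were not named. Of the genes the rule takes, those not printed are covered by the counts.

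Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, adjusted over the pathway lists and over the cell type lists separately, and again with the estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance. The share of the WT IL-10 response seen with 10-DE is the slope through the origin of log2 changes. Groups with no effect were simulated 20 times against shared controls, from each gene's mean over all samples and its dispersion. Replicates of each group were compared by a chi-square per gene over genes with more than 50 counts in the pair, and every pair differed by more than sampling noise, so none was taken as a repeat of the same library. Alternatives were RLE and upper quartile factors, library size alone, no filter, a filter of at least 1 CPM in 2 samples, DESeq2 1.42.0, limma-voom, only the 4 samples compared, the replicate number as a block, the robust fit, protein-coding genes only, limma on log2 of the FPKM plus 1 or 0.1 (genes at a mean of at least 1) or plus 1 with no filter, and leaving out each sample. An alternative was added after the data were seen, namely an offset per library from splines of GC content and length of each gene's longest GENCODE 29 transcript, known for 99.96% of tested genes.

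The steps were tested on simulated data. With 200 genes changed in simulated WT IL-10 against PBS samples and 13791 genes tested, 60% of 1.25-fold, 70% of 1.5-fold, 86% of 2-fold and 100% of 4-fold changes were called, 50 genes at each size, and 3.45% of calls were false. A slope of 0.4 was recovered as 0.401, and a list shifted by 0.3 had an adjusted p of 1.38e-17 with the preset and 0.0111 with the estimated correlation, with 0 of 18 unshifted lists called. With a GC trend added to the simulated libraries, 10% of 1.25-fold changes were called without and 40% with the offsets, over 13786 genes. Depth was 15882574 to 19697334 counts per sample, and reads without molecular identifiers are not independent molecules, so floors of 3 counts cover counting error only. Near-identical genes (CCL3 and CCL4 with their copies, XCL1 and XCL2, GIMAP genes) may share reads, and IL10RB and NME2 overlap read-through genes, so these values are uncertain. The strand setting is not known, so IFNG and GZMB reads cannot be told from those of genes annotated on the other strand at the same place. Figures were drawn with matplotlib.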

Results

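RNA was sequenced from human CD8+ T cells, the cytotoxic lineage of T cells, that had been taken from blood mononuclear cells by magnetic selection. The cells were activated for 3 days through CD3 and CD28, the T cell receptor complex and its costimulatory partner. They were then cultured for 24 h with PBS or with 10 nM of 1 of 3 forms of interleukin-10. The PBS samples were taken as the untreated control from their labels. WT IL-10 is the natural cytokine, which signals through its receptor chains, encoded by IL10RA and IL10RB, to the transcription factor STAT3. Super-10 and 10-DE are engineered versions of it. The comparisons ask how activated CD8+ T cells respond to each protein, and how the responses differ. There were 4 groups of 2 samples, 8 in all, and each sample held between 15882574 and 19697334 counts over genes, with 19400 to 21773 genes detected. The labels do not say that the samples of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. A count of 3 corresponded to between 0.152 and 0.189 CPM. Of 58735 genes listed, 14058 were expressed highly enough to be tested. Mitochondrial transcripts took 0.826% to 0.955% of counts in PBS, 0.849% to 0.868% in WT IL-10, 0.619% to 0.74% in super-10 and 0.744% to 0.76% in 10-DE samples. Libraries of the same group also differed along the GC content of genes. The median log2 deviation of the 10% of genes highest in GC, minus that of the 10% lowest, was -0.15 in PBS replicate 1 and 0.15 in PBS replicate 2. It was 0.14 and 0.068 in the super-10 samples, 0.017 and -0.032 in the WT IL-10 samples, and -4.7e-04 and -0.20 in the 10-DE samples. Levels are given as TMM-normalised CPM, mean ± SD of 2 samples. Changes are log2 fold changes from edgeR's quasi-likelihood fit with their standard error (SE). A gene was called when its Benjamini-Hochberg adjusted p was under 0.05.

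WT IL-10 raised GZMB, SOCS3 and IL9 and lowered CCL22, CCL17, IL13 and MX1. GZMB, which encodes the granule protease granzyme B (chromosome 14, 24630954 to 24634267 of GRCh38), rose from 838 ± 29.1 to 2483 ± 64.2 CPM, a 2.96-fold change (log2 1.57, SE 0.0443, adjusted p 8.11e-20). SOCS3, the STAT3-induced feedback inhibitor of cytokine receptors (chromosome 17, 78356778 to 78360077), rose 2.99-fold from 28.1 ± 1.27 to 84.2 ± 4.89 CPM. IL9, a cytokine gene, rose 5.04-fold from 21.1 ± 0.0317 to 106 ± 0.955 CPM, and TNFRSF8, which encodes the activation receptor CD30, rose 2.80-fold. The chemokine gene CCL22 fell from 54.8 ± 0.587 to 9.51 ± 0.21 CPM (log2 -2.53, SE 0.11, adjusted p 1.13e-15) and CCL17, which encodes another ligand of the receptor CCR4, fell from 114 ± 4.65 to 21.4 ± 0.0515 CPM. In total 987 genes were called, 451 higher and 536 lower, of which 125 changed at least 2-fold.

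By gene list, 15 of 24 tested cytokine and chemokine genes fell and 3 rose (3 higher and 17 lower when adjusted over the list alone). Those that fell included IL13 (136 ± 5.45 to 46.1 ± 1.26 CPM), IL5 (224 ± 28.5 to 108 ± 3.6 CPM), LTA, which encodes lymphotoxin alpha (log2 -1.36), TNF (log2 -0.97) and CSF2 (log2 -0.99). IFNG, the gene of interferon gamma, was at 218 ± 16.6 CPM with PBS and 203 ± 4.98 CPM with WT IL-10 (log2 -0.10, SE 0.0587, adjusted p 0.36). The 3 that rose were IL9, IL22 and IL26. Outside the lists, the interleukin gene IL17F rose from 0.346 ± 0.189 to 3.01 ± 0.364 CPM. In the type I interferon response list 20 of 29 genes fell and none rose (22 lower over the list alone). Among them were the antiviral genes MX1 (35.1 ± 0.285 to 11.8 ± 1.51 CPM), IFIT1 (log2 -2.12), IFI44L (log2 -1.81) and OAS3 (log2 -0.68). Of 24 interferon-gamma response genes, 8 fell, including CXCL10 (log2 -0.61) and GBP1 (log2 -0.37), and 1, GBP2, rose (2 higher and 12 lower over the list alone). Cholesterol and fatty acid synthesis genes fell in 12 of 24 cases with no rise (14 lower over the list alone), among them SCD, the stearoyl-CoA desaturase (log2 -0.40), FADS1 (log2 -0.44) and the sterol-regulated INSIG1 (log2 -0.36).

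Of 16 cytotoxic granule genes, 5 rose with WT IL-10 and none fell (6 higher over the list alone): GZMB, GNLY (granulysin, log2 0.83), GZMH (log2 0.55), GZMA (log2 0.30) and NKG7 (log2 0.17). PRF1, the perforin gene, was at 236 ± 24.8 CPM with PBS and 269 ± 15.7 CPM with WT IL-10 (log2 0.19, SE 0.0654, adjusted p 0.0915). In the list of STAT3 and cytokine feedback genes, 12 of 20 rose and 3 fell (12 and 5 over the list alone). BCL3 rose by 0.80, BCL6 by 0.71, JUNB by 0.64 and STAT3 itself by 0.48 on the log2 scale, and the 3 that fell were the feedback inhibitors SOCS1 (log2 -0.43) and CISH (log2 -0.47) and the cytokine gene OSM (log2 -0.34). IL10RA, the gene of the ligand-binding receptor chain, was lower, at 120 ± 2.19 against 155 ± 5.15 CPM (log2 -0.37, adjusted p 1.21e-04). IL10 itself was near the floor, at 0.213 ± 0.0744 CPM with PBS and 0.936 ± 0.145 CPM with WT IL-10 (log2 2.11, adjusted p 0.0456). That call ended under 13 alternative settings. IL10RB lay under 1 CPM in every group and overlaps another annotated gene, so its level is uncertain. Effector transcription factors rose in 2 and fell in 5 of 23 cases (3 and 8 over the list alone), with NR4A3 at log2 -1.76 and GATA3 at log2 -0.57. Glycolysis and hypoxia genes rose in 6 and fell in 1 of 28 cases (8 and 2 over the list alone), with LDHA, the lactate dehydrogenase gene, at log2 0.39. Cell cycle genes of the G2 and M phases rose in 4 of 24 cases (6 over the list alone). Of 19 p53 and apoptosis genes 3 fell (1 higher and 4 lower over the list alone), among them BCL2L1, which encodes the survival protein BCL-XL (log2 -0.86).

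In camera, a test of a list against all other genes with a preset correlation of 0.01, 10 of the 19 pathway lists passed, each of those described above. With a correlation estimated per list 5 passed: type I interferon (adjusted p 0.00957), cytokines and chemokines (adjusted p 0.0186), and cytotoxic granule, interferon-gamma and cholesterol genes (adjusted p 0.0405 each). The others then had adjusted p of 0.135 (STAT3 feedback, glycolysis, p53), 0.064 (effector transcription factors) and 0.194 (G2 and M phase). The count of called genes fell to 440 without WT IL-10 replicate 1 and to 436 without WT IL-10 replicate 2, and it was 645, 634 and 268 in the limma tests on FPKM. It was 1555 after a correction for GC content and transcript length chosen after the data were seen, with 892 higher and 663 lower genes, and library size alone as the scaling gave 278 higher and 720 lower genes. Higher genes also outnumbered lower ones without PBS replicate 2 (613 and 568).

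**Figure D1:**
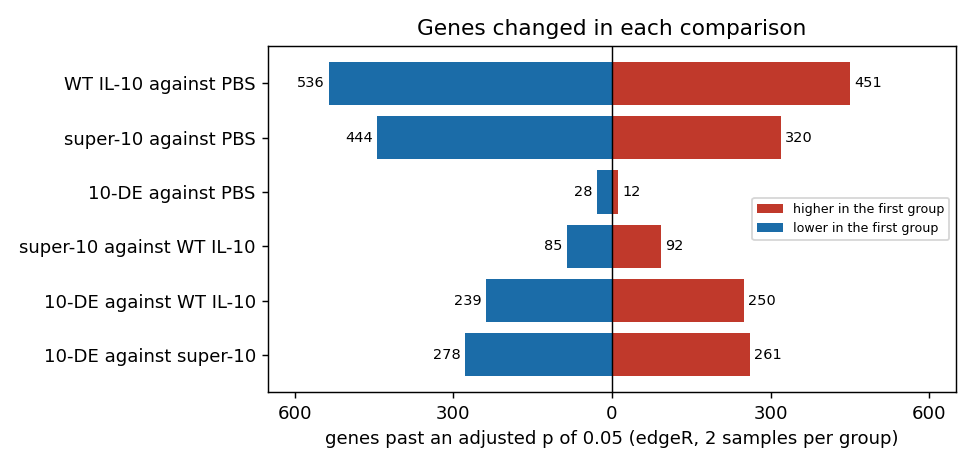
Number of genes past an adjusted p of 0.05 in each of the 6 comparisons (horizontal axis, number of genes; edgeR, 2 samples per group), split into genes higher (red, to the right) and lower (blue, to the left) in the first-named group. The bars for 10-DE against PBS hold 12 and 28 genes, and those for WT IL-10 against PBS hold 451 and 536.

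Super-10 moved many of the genes that WT IL-10 moved, and in addition raised IFNG. IFNG (chromosome 12, 68154768 to 68159747) rose from 218 ± 16.6 CPM with PBS to 544 ± 27 CPM (log2 1.32, SE 0.0581, adjusted p 2.52e-15). TBX21, the gene of T-bet, the transcription factor that drives interferon gamma, rose by 0.49 on the log2 scale. IL9 rose 4.52-fold to 95.2 ± 2.41 CPM, GZMB 1.90-fold to 1596 ± 1.26 CPM, SOCS3 2.03-fold to 57.1 ± 0.374 CPM and TNFRSF8 2.23-fold to 153 ± 9.08 CPM. CCL22 fell to 12.8 ± 0.68 CPM and MX1 to 15.1 ± 0.625 CPM (log2 -1.22, SE 0.109, adjusted p 1.28e-08). THY1, a surface glycoprotein gene, fell from 7.95 ± 0.00702 to 2.23 ± 0.317 CPM, and NR4A3, an early gene of T cell receptor signalling, from 10.3 ± 0.976 to 2.96 ± 1.05 CPM. The interleukin gene IL17F rose from 0.346 ± 0.189 to 2.05 ± 0.0625 CPM. In total 764 genes were called, 320 higher and 444 lower, 92 of them by at least 2-fold.

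Type I interferon genes fell in 17 of 29 cases with super-10 and rose in none (22 lower over the list alone), and cytokine and chemokine genes fell in 14 of 24 and rose in 2, IFNG and IL9 (15 and 2 over the list alone). IL13 was lower by 0.92, IL5 by 0.70 and CCL5 by 0.53 on the log2 scale, while TNF was at log2 -0.15 and not called. STAT3 and cytokine feedback genes rose in 8 of 20 cases and fell in 1, CISH (10 and 3 over the list alone), with PIM1, a STAT-induced kinase gene, at log2 0.53. Effector transcription factors rose in 3 and fell in 7 of 23 cases (3 and 11 over the list alone), the falls including the early-response genes EGR2 (log2 -0.89), EGR3 (log2 -0.95) and NR4A2 (log2 -0.86). Cholesterol and fatty acid genes fell in 6 of 24 cases (11 over the list alone), amino acid and ER stress genes rose in 4 of 20 (6 higher and 1 lower over the list alone), with XBP1, a regulator of the unfolded protein response, at log2 0.37, and glycolysis genes rose in 4 of 28 (4 over the list alone). Among cytotoxic granule genes, which did not pass as a list, GZMB was the 1 that rose, SRGN (log2 -0.18) and SERPINB9 (log2 -0.28) fell, and GNLY stood at log2 0.09 and PRF1 at log2 -0.04, both uncalled. IL10 (1.02 ± 0.337 CPM) was called at an adjusted p of 0.0415 and lost the call under 12 alternatives, and IL10RA was at log2 -0.18 (adjusted p 0.0854).

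Of the 19 pathway lists 7 passed camera for super-10 against PBS; with the estimated correlation 1 did, type I interferon (adjusted p 0.0153). The other 6 then had adjusted p of 0.0611 (cytokines), 0.227 (STAT3 feedback and glycolysis), 0.114 (effector transcription factors and cholesterol) and 0.281 (amino acid and ER stress). The gene count was 1330 without PBS replicate 2 (688 higher and 642 lower), 319 without super-10 replicate 1 and 334 without super-10 replicate 2, 501 with DESeq2, 470 with the 4 samples alone and 459, 457 and 139 on FPKM. It was 1320 after GC and length correction, with 696 higher and 624 lower genes, and library size scaling gave 243 higher and 544 lower genes.

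**Figure D2:**
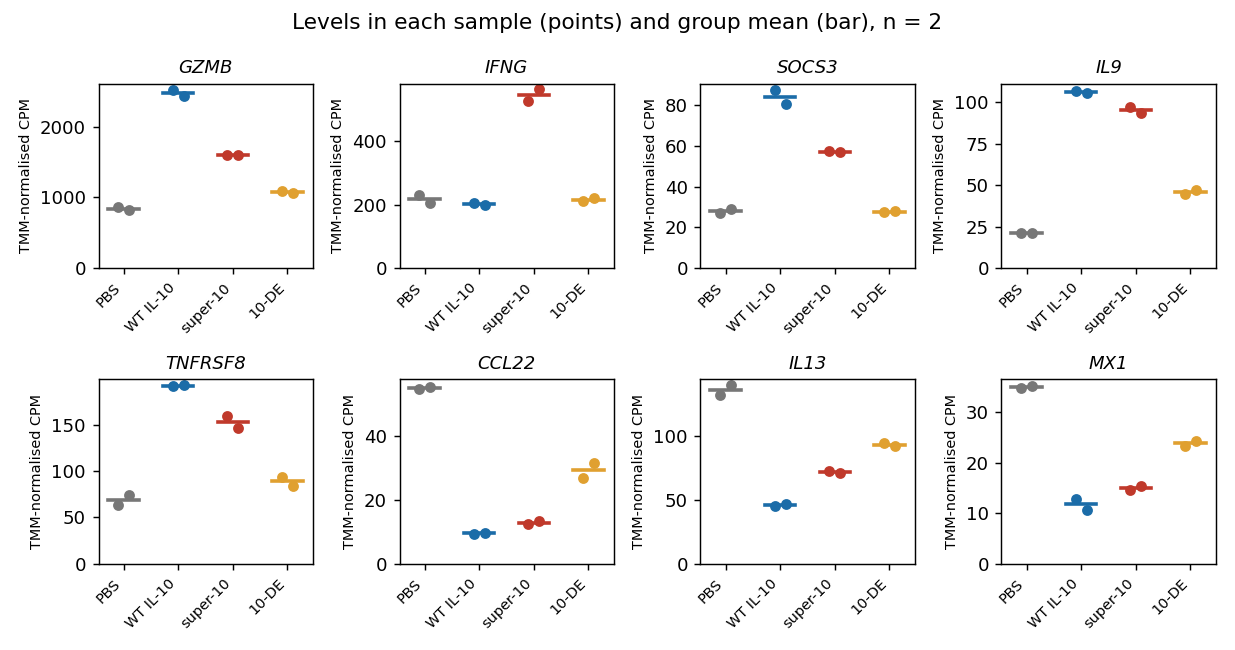
Levels of 8 genes in each sample (points, TMM-normalised CPM on a linear axis from 0) with the group mean as a bar, for PBS, WT IL-10, super-10 and 10-DE, 2 samples each. IFNG stands at 544 CPM with super-10 and between 203 and 218 CPM in the other groups, and SOCS3 with 10-DE (27.6 CPM) lies at the PBS level (28.1 CPM).

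10-DE raised IL9 and GZMB and lowered CCL22, LTA and IL13, over fewer called genes than the other proteins. IL9 rose 2.18-fold from 21.1 ± 0.0317 to 46.1 ± 1.82 CPM (log2 1.13, SE 0.0802, adjusted p 1.04e-09), GZMB 1.28-fold to 1077 ± 22.7 CPM (adjusted p 1.99e-05) and TNFRSF8 1.30-fold to 88.9 ± 7.17 CPM. CCL22 fell to 29.1 ± 3.24 CPM (log2 -0.91), LTA from 110 ± 3.85 to 72.6 ± 0.543 CPM (log2 -0.60), IL13 to 93.3 ± 1.82 CPM (log2 -0.54), TNF to 15.5 ± 0.698 CPM (log2 -0.64), NR4A3 to 4.6 ± 0.256 CPM (log2 -1.17) and MX1 to 23.8 ± 0.657 CPM (log2 -0.56). SOCS3 stood at 27.6 ± 0.438 CPM against 28.1 ± 1.27 CPM with PBS, a log2 change of -0.024 with an interval of -0.19 to 0.15, and IFNG at 216 ± 7.64 against 218 ± 16.6 CPM (log2 -0.015, interval -0.13 to 0.10). In total 40 genes were called, 12 higher and 28 lower, 5 of them by at least 2-fold, and 1040 had an unadjusted p under 0.05.

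Among the lists, cytokine and chemokine genes fell in 7 of 24 cases with 10-DE and rose in 1, IL9 (9 and 1 over the list alone). Type I interferon genes fell in 2 of 29 cases, MX1 and OAS3 (log2 -0.40), with 10 lower over the list alone. GZMB was the 1 of 16 granule genes to rise (2 over the list alone), and NR4A3 the 1 of 23 effector transcription factors to fall (3 over the list alone). FASN, the fatty acid synthase gene, fell from 408 ± 47.6 to 308 ± 20.8 CPM (log2 -0.40), and was lower with 10-DE than with WT IL-10 or super-10 (log2 -0.32 and -0.30, both called). BCL2L1 fell to 96.3 ± 3.73 CPM (log2 -0.41), and GIMAP4 (log2 0.36), GIMAP7 (log2 0.36) and CD28 (log2 0.30), a costimulatory receptor gene, rose. The CD28 call ended under 10 alternatives, and those of TNFRSF8, TNF, MX1, OAS3, FASN, GIMAP4 and GIMAP7 under 5 each. That of NR4A3 ended under 4, that of BCL2L1 under 2, and those of GZMB, LTA and CCL22 under 1 each, on FPKM plus 1 with no filter. PRF1 (log2 -0.09), IL10RA (log2 -0.13) and IL10 (log2 0.10) were not called.

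Of the 19 pathway lists 5 passed camera for 10-DE against PBS, among them G2 and M phase genes with no called member (0 over the list alone), and with the estimated correlation 1 did, type I interferon (adjusted p 0.04). The adjusted p was then 0.0683 for cytokines, 0.208 for granule genes, 0.0821 for effector transcription factors and 0.49 for G2 and M phase genes. The gene count was 359 without PBS replicate 1, 99 without PBS replicate 2, 25 without 10-DE replicate 1 and 11 without 10-DE replicate 2, and it was 96 after GC and length correction, 93 with no low-count filter, 15 with the 4 samples alone and 12, 10 and 9 on FPKM, the last with 5 higher and 4 lower genes.

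**Figure D3:**
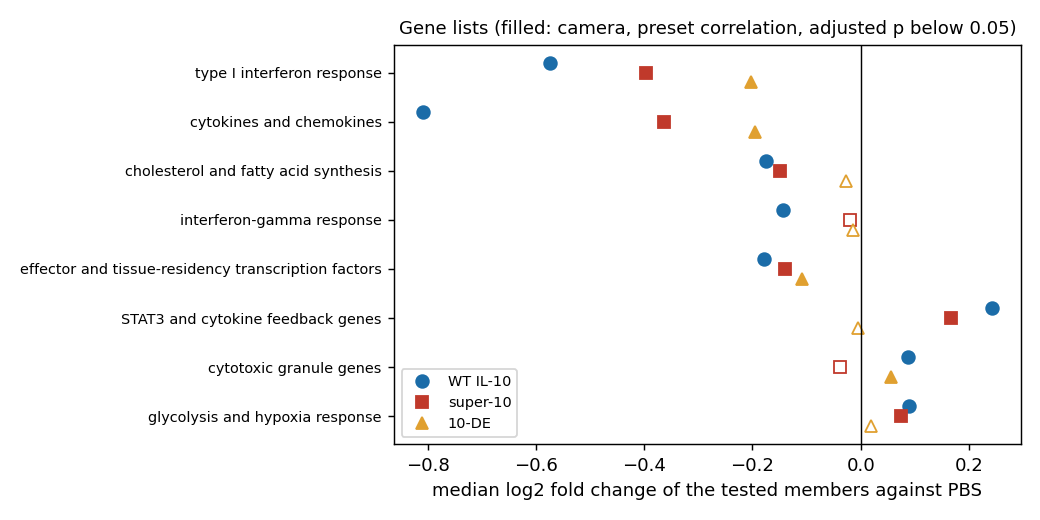
Median log2 fold change against PBS of the tested members of 8 gene lists (horizontal axis) for WT IL-10 (circles), super-10 (squares) and 10-DE (triangles). Filled symbols mark lists with an adjusted p under 0.05 in camera with the preset correlation of 0.01, and the type I interferon list lies at -0.57, -0.40 and -0.20. With the estimated correlation, 5 of the 19 pathway lists passed for WT IL-10, 1 for super-10 and 1 for 10-DE.

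Compared directly with WT IL-10, super-10 gave more IFNG, LTA and IL13 transcript and less GZMB, GNLY and SOCS3. IFNG was 2.69-fold higher (544 ± 27 against 203 ± 4.98 CPM, log2 1.43, SE 0.0585, adjusted p 1.29e-15). LTA was 1.67-fold, IL13 1.55-fold, CSF2 1.58-fold and OSM 1.51-fold higher. With super-10, LTA (71.9 CPM), IL13 (71.8 CPM) and CSF2 (58.4 CPM) still had means under those with PBS (110, 136 and 73.1 CPM). GZMB and SOCS3 stayed above PBS with super-10, by 0.93 and 1.02 on the log2 scale. GZMB was lower, at 1596 ± 1.26 against 2483 ± 64.2 CPM (log2 -0.64, SE 0.0433, adjusted p 1.79e-10), as were GNLY (41.8 ± 1.53 against 69.6 ± 0.727 CPM), GZMA (322 ± 18.7 against 428 ± 3.67 CPM), SOCS3 (57.1 ± 0.374 against 84.2 ± 4.89 CPM) and CXCR6, a chemokine receptor gene (34.9 ± 2.32 against 62.9 ± 5.5 CPM). The calls of SOCS3, CSF2, OSM, GZMA and CXCR6 between the 2 proteins ended under 1 alternative each. IL10, IL10RA and PRF1 were not called (adjusted p 0.968, 0.157 and 0.104). In total 177 genes were called, 92 higher and 85 lower, 15 by at least 2-fold.

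Of 24 cytokine and chemokine genes 9 were higher and 1, IL26, lower with super-10 than with WT IL-10 (12 and 4 over the list alone; the IL26 call was lost under 10 alternatives), and of 16 granule genes 5 were lower and none higher (8 lower over the list alone). Interferon-gamma response genes were higher in 5 of 24 cases (10 over the list alone), among them TAP1 (log2 0.36) and IRF1 (log2 0.30), the first a peptide transporter of antigen presentation and the second an interferon-induced transcription factor. Against PBS, super-10 raised 1 of the 24 and lowered 3 (5 and 3 over the list alone). The list median was then log2 -0.02 (camera adjusted p 0.909 with the preset correlation). WT IL-10 raised 1 and lowered 8 against PBS, with a median of log2 -0.14. Of 29 type I interferon genes 1, IFIT1, was higher (1 over the list alone), a call lost under 8 alternatives, among them leaving out any 1 sample of either group. In camera with the preset correlation 8 lists passed, the other 4 being NK-type receptors, G2 and M phase, cholesterol, and amino acid and ER stress genes. Those 4 lists held 0, 0, 0 and 1 called members, the last being XBP1. Over the list alone the numbers were 0, 2 (1 higher and 1 lower), 0 and 1. With the estimated correlation none passed: adjusted p was 0.0504 for the cytokine, granule and 2 interferon lists, 0.312 for NK-type receptors, cholesterol and amino acid genes and 0.387 for G2 and M phase genes. The gene count was 454 and 464 without PBS replicate 1 or 2, 45 and 42 without WT IL-10 replicate 1 or 2, and 63 and 58 without super-10 replicate 1 or 2. It was 352 after GC and length correction, 267 with no low-count filter, 567 with the 4 samples alone and 58, 58 and 14 on FPKM, and library size scaling gave 109 higher and 64 lower genes. Lower genes outnumbered higher ones in other settings: 145 higher and 207 lower with the correction, 117 and 150 with no filter, 252 and 315 with the 4 samples alone, 199 and 255 or 265 without PBS replicate 1 or 2, and 28 and 30 without super-10 replicate 2.

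Compared directly with WT IL-10, 10-DE left SOCS3, GZMB and IL9 lower and CCL17, CCL22, IL13 and MX1 higher. SOCS3 was at 27.6 ± 0.438 against 84.2 ± 4.89 CPM (log2 -1.61, SE 0.0805, adjusted p 6.78e-14) and GZMB at 1077 ± 22.7 against 2483 ± 64.2 CPM (log2 -1.21, SE 0.0438, adjusted p 5.63e-17). IL9 was at 46.1 ± 1.82 against 106 ± 0.955 CPM, GNLY at 41.9 ± 0.439 against 69.6 ± 0.727 CPM, and PRF1 at 221 ± 5.29 against 269 ± 15.7 CPM (log2 -0.28, adjusted p 0.0122, a call lost under 6 alternatives). CCL17 was 3.79-fold, CCL22 3.06-fold, IL13 2.02-fold and MX1 2.03-fold higher with 10-DE, and IL10RA was higher by 0.24 on the log2 scale (adjusted p 0.0224, a call lost under 5 alternatives). IFNG did not differ beyond the spread (log2 0.09, SE 0.0586, adjusted p 0.531). In total 489 genes were called, 250 higher and 239 lower, 60 by at least 2-fold. Cytokine and chemokine genes were higher in 13 and lower in 3 of 24 cases (15 and 3 over the list alone), type I interferon genes higher in 8 of 29 (18 over the list alone), cholesterol genes higher in 10 and lower in 1 of 24 (13 and 2 over the list alone), STAT3 feedback genes lower in 10 of 20 (1 higher and 12 lower over the list alone), granule genes lower in 5 of 16 (5 over the list alone) and interferon-gamma genes higher in 4 of 24 (10 over the list alone). With glycolysis genes (1 higher and 2 lower of 28; 1 and 6 over the list alone) these 7 lists passed camera. With the estimated correlation 2 did, type I interferon (adjusted p 0.0194) and cytokines (adjusted p 0.0272), and the adjusted p was 0.0606 for cholesterol and interferon-gamma genes, 0.0747 for granule genes, 0.108 for STAT3 feedback genes and 0.154 for glycolysis genes. The gene count was 932 without either PBS replicate, 141 and 161 without WT IL-10 replicate 1 or 2, and 257 and 186 without 10-DE replicate 1 or 2. It was 882 after GC and length correction, 311 with DESeq2, 1019 with the 4 samples alone and 250, 251 and 42 on FPKM, and library size scaling gave 319 higher and 170 lower genes. Lower genes outnumbered higher ones after GC and length correction (406 higher and 476 lower), with limma-voom (234 and 245), without either PBS replicate (433 and 499 each) and without 10-DE replicate 1 (121 and 136).

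Compared with super-10, 10-DE gave less IFNG (216 ± 7.64 against 544 ± 27 CPM, log2 -1.33, SE 0.0581, adjusted p 5.61e-15), less SOCS3 (log2 -1.05), less IL9 (log2 -1.05), less GZMB (log2 -0.57), less PIM1 (log2 -0.52) and less TBX21 (log2 -0.52). CCL17 was higher with 10-DE, at 81.1 ± 4.72 against 34 ± 1.47 CPM, CCL22 at 29.1 ± 3.24 against 12.8 ± 0.68 CPM and CCL5 by 0.50 on the log2 scale. TNFSF14, a costimulatory ligand gene, was higher by 0.51. IL10, IL10RA and PRF1 were not called (adjusted p 0.0593, 0.754 and 0.724). In total 539 genes were called, 261 higher and 278 lower, 41 by at least 2-fold. STAT3 feedback genes were lower in 7 of 20 cases (8 over the list alone), type I interferon genes higher in 5 of 29 (8 higher and 1 lower over the list alone), cytokines higher in 7 and lower in 3 of 24 (11 and 3 over the list alone), chemokine receptors and integrins higher in 6 and lower in 1 of 21 (7 and 1 over the list alone), cholesterol genes higher in 3 and lower in 1 of 24 (7 and 1 over the list alone) and amino acid and ER stress genes lower in 4 of 20 (1 higher and 4 lower over the list alone). All 6 of these lists passed camera with the preset correlation and none with the estimated one (adjusted p 0.0926 for type I interferon, 0.284 for STAT3 feedback, cytokines and cholesterol, 0.311 for chemokine receptors and 0.32 for amino acid genes). The gene count was 1174 and 1177 without PBS replicate 1 or 2, 112 and 216 without super-10 replicate 1 or 2, and 302 and 147 without 10-DE replicate 1 or 2. It was 898 with the 4 samples alone and 253, 249 and 23 on FPKM. Higher genes outnumbered lower ones on FPKM (159 and 94, 158 and 91, 12 and 11), with upper quartile factors (274 and 253), library size alone (285 and 245), no filter (327 and 264) and GC and length correction (385 and 338). They did so too without WT IL-10 replicate 1 (197 and 174) or 2 (192 and 186), super-10 replicate 1 (60 and 52) or 10-DE replicate 2 (84 and 63).

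The genes called against PBS overlapped between the 3 proteins. WT IL-10 and super-10 shared 164 genes called higher and 288 called lower against PBS, where independent lists would share 10.3 and 16.9, and 2 genes were called in opposite directions. 10-DE shared 11 higher and 20 lower genes with WT IL-10 (0.385 and 1.07 for independent lists) and 11 higher and 22 lower with super-10 (0.273 and 0.884). The numbers for independent lists take no account of the PBS samples shared by the 3 comparisons. Because all 3 were set against the same PBS samples, changes with no effect at all would already correlate across genes, at r = 0.48 in 20 simulations for WT IL-10 and super-10, where the data gave r = 0.63. The covariance of their log2 changes was 0.105 against 0.0376 simulated. For WT IL-10 and 10-DE it was 0.0646 against 0.0378, with r = 0.49 against 0.50 simulated, and for super-10 and 10-DE 0.0633 against 0.0382, with r = 0.48 against 0.50 simulated. The 2 PBS samples could not be split into groups of at least 2, so part of the excess may come from the shared controls. Over the 1297 genes called for WT IL-10 or super-10, the slope through the origin of the 10-DE changes on the WT IL-10 changes was 0.378 (0.373 after the simulated shared-control part was taken off), the median ratio was 0.325, and 86.7% of genes had the same sign, against 66.5% simulated with no effect. The simulated values used the genes picked in the data, which were not picked anew in each simulation. They therefore leave out selection on the shared PBS samples. They also gave every group the same spread per gene and no GC trends. The PBS samples in fact lay further apart (chi-square per gene 7.31) than those of the other groups (2.24 to 3.64). For both reasons the simulated values may understate the shared-control part. The slope over single-sample combinations ranged from 0.344 to 0.378 (SD 0.0123, 8 combinations). These combinations share samples, keep the genes chosen with all samples and use differences of log2 CPM, so the SD is not an error of the slope of 0.378. The slope over called genes was 0.487 without PBS replicate 1, 0.59 without PBS replicate 2 and 0.321 without super-10 replicate 2. The slope of super-10 on WT IL-10 over the same genes was 0.794.

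Genes of the cell type lists differed widely in level. CD8A, which encodes a chain of the CD8 coreceptor, lay between 707 and 840 CPM per sample with no normalisation factor applied. CD4 lay between 1.53 and 2.27 CPM, the B cell gene MS4A1 between 0.437 and 1.77 CPM and the monocyte gene CD14 between 0.376 and 1.38 CPM. Other listed genes were higher: BATF3 (262 to 329 CPM) and CCL17 (21 to 119 CPM) of the dendritic cell list, CCR4 (189 to 236 CPM) of the CD4 T cell list and XCL1 (22.5 to 50.4 CPM) of the NK cell list. The 3 gamma-delta T cell genes lay between 4.25 and 39.1 CPM. Of the 8 marker lists none passed camera for WT IL-10 or super-10 against PBS, or in the comparisons between proteins. In 10-DE against PBS the dendritic cell list (0 higher and 1 lower, CCL17, of 4, and 1 lower over the list alone) and the platelet and red cell list (0 called of 5, and 1 lower over the list alone) passed camera at an adjusted p of 0.0489 each, or 0.252 with the estimated correlation. More lists passed fry against PBS. With WT IL-10 these were dendritic cell (adjusted p 5.56e-04), monocyte (0.00317), CD4 T cell and platelet (0.0117 each) and B cell genes (0.0177). Their median log2 changes were -0.32, 0.89, -0.088, -0.33 and 0.12 in that order. With super-10 the lists were dendritic cell (0.00602), monocyte, B cell and gamma-delta (0.034 each) and platelet genes (0.0396). Their medians were -0.025, 0.81, 0.0085, -0.45 and -0.17. With 10-DE the lists were monocyte (0.0221, median 0.76) and dendritic cell genes (0.0335, median -0.34). Only 3 of 16 monocyte and 4 of 10 dendritic cell genes were tested. BATF3, CCR4, CCR8 and XCL1 also stand in the pathway lists, so a moved list need not mean a change in the mix of cells, which was not tested. Of the 50 tested marker genes, 2 were called higher and 6 lower with WT IL-10 against PBS: for example, CSF1R, a monocyte gene, rose from 0.372 ± 0.149 to 2.19 ± 0.528 CPM, and CCR8 and FOXP3, both in the CD4 T cell list, fell by 1.05 and 0.47 on the log2 scale. The CSF1R call ended under 2 alternatives. With super-10 against PBS, 2 were higher and 7 lower, among them 2 of 3 gamma-delta T cell genes (list median log2 -0.45; adjusted p 0.317 with the preset correlation, 0.591 with the estimated one and 0.034 with fry) and 1 of 9 CD8 T cell identity genes, CD5 (log2 -0.22), all lower. Of 10 NK cell genes 1 was higher and 1 lower.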

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

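The GC and length correction, and the SD of the slope over single-library combinations (0.0123, 8 combinations), were chosen after the data were seen. That SD was taken after the SD of the slopes of the 2 10-DE samples was seen to be very small, and it is not an error of the slope. The other alternatives were planned. Of 160 named results that were called, none reversed under any alternative, 56 stayed called under all alternatives that tested them, among them SOCS3 and GZMB with WT IL-10 and IFNG with super-10, and 423 of their 3603 alternatives ended the call. The numbers of genes called were less steady. For WT IL-10 against PBS (987) the count was 645, 634 and 268 on FPKM (plus 1, plus 0.1, plus 1 with no filter) and 1555 with GC and length offsets. For super-10 against PBS (764) it was 501 with DESeq2, 470 with only the 2 groups compared, 459, 457 and 139 on FPKM and 1320 with offsets. For 10-DE against PBS (40) it was 93 with no filter, 15 with 2 groups, 12, 10 and 9 on FPKM and 96 with offsets. For super-10 against WT IL-10 (177) it was 267 with no filter, 567 with 2 groups, 58, 58 and 14 on FPKM and 352 with offsets. For 10-DE against WT IL-10 (489) it was 311 with DESeq2, 1019 with 2 groups, 250, 251 and 42 on FPKM and 882 with offsets. For 10-DE against super-10 (539) it was 898 with 2 groups and 253, 249 and 23 on FPKM. The 2-group fit uses 4 samples and its own spread by construction, while the main fit shares its estimate of the spread over all groups. The PBS samples lay further apart (chi-square per gene 7.31) than those of WT IL-10 (2.24), super-10 (3.13) or 10-DE (3.64). That PBS spread enters the main fit also in comparisons between proteins, where the 2-group counts were higher (567, 1019 and 898). Against PBS the 2-group counts were lower (679, 470 and 15). Otherwise the cause was not tested. The offsets kept 982 of 987, 758 of 764, 39 of 40, 174 of 177, 486 of 489 and 442 of 539 calls, in the order of comparisons above.

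The share of calls that were higher was 45.7%, 41.9%, 30%, 52%, 51.1% and 48.4% in that order. With library size alone it was 27.9%, 30.9%, 25%, 63%, 65.2% and 53.8%, and with offsets 57.4%, 52.7%, 40.6%, 41.2%, 46% and 53.3%. On FPKM plus 1 with a filter it was 27.9%, 29.8%, 25%, 63.8%, 67.2% and 62.8%. Library size alone moved the median log2 change of all genes by at most 0.04.

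Leaving out 1 sample, where the lone sample left is assumed to vary like the other groups, gave 436 to 1205 genes for WT IL-10 against PBS, 319 to 1330 for super-10 against PBS, 11 to 359 for 10-DE against PBS, 42 to 464 for super-10 against WT IL-10, 141 to 932 for 10-DE against WT IL-10 and 112 to 1177 for 10-DE against super-10. The lists past the test numbered 8 to 10, 6 to 8, 3 to 5, 4 to 7, 6 to 7 and 3 to 6 in that order, and the share of the WT IL-10 response seen with 10-DE was 0.321 to 0.59.

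Lists past the test numbered 10, 7, 5, 8, 7 and 6. With the estimated correlation they were 5, 1, 1, 0, 2 and 0. That setting also sets the test against the 4 residual degrees of freedom. Estimated correlations lay under the preset 0.01 for lists such as cytokine (0.00558), type I interferon (-0.0206), granule (-0.0311) and interferon-gamma (-0.0341) genes. For these lists that argues against a higher correlation as what weakened the test. They lay above it for others, such as STAT3 feedback (0.103), G2 and M phase (0.13), cholesterol (0.058) and amino acid genes (0.0785), where the 2 parts were not separated. The count with fry was 11 for super-10 against PBS. The share (0.378) was 0.418 over genes called for super-10, 0.456 over genes called for WT IL-10 with the slope against super-10, and 0.335 with a filter of at least 1 CPM in 2 samples; the cause was not tested. No strong pairing by replicate number was seen, as deviations of samples with the same number correlated at -0.0155 to 0.0486. A weak pairing could be hidden by the GC trends of single libraries, and the labels do not say what a number shares. The replicate block gave 841, 646, 36, 139, 404 and 414 genes, 9, 6, 5, 7, 6 and 4 lists and a share of 0.384.

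The changes that took the other sign were all of uncalled genes, and the cause was not tested. With GC and length offsets SOCS3 in 10-DE against PBS was at log2 0.022 and PRF1 in 10-DE against super-10 at 0.029. The log2 ranges over leaving out 1 sample were, in super-10 against PBS, -0.82 to 0.085 for IL10RB and -0.14 to 0.072 for PRF1. In 10-DE against PBS they were -0.21 to 0.50 for IL10, -1.76 to 0.31 for IL10RB, -0.067 to 0.024 for SOCS3, -0.089 to 0.068 for IFNG and -0.19 to 0.018 for PRF1. They were -0.27 to 0.41 for IL10 in super-10 against WT IL-10, -0.17 to 1.90 for IL10RB in 10-DE against WT IL-10, and -1.46 to 0.62 for IL10RB and -0.13 to 0.027 for PRF1 in 10-DE against super-10. The group means of IL10 and IL10RB, near or under 1 CPM, stand close to the floor of 3 counts (0.152 to 0.189 CPM), and low depth was not separated from reads lost to the gene that overlaps IL10RB.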

Other observations

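The tests in this part were chosen after the values they concern had been seen, except the test of GC trends for the count without PBS replicate 1. GIMAP genes, which encode GTPases of lymphocytes and lie together on chromosome 7, were looked at after 2 of them were seen among the called genes. With WT IL-10, 5 of the 7 tested rose: GIMAP7 from 76.5 to 138 CPM (log2 0.85), GIMAP4 from 120 to 206 CPM (log2 0.79), GIMAP8 (log2 0.51), GIMAP1 (log2 0.46) and GIMAP6 (log2 0.35). GIMAP2 (log2 0.21) and GIMAP5 (log2 0.60, SE 0.39) were not called. With super-10, GIMAP4, GIMAP7, GIMAP8 and GIMAP6 rose, by 0.66, 0.63, 0.50 and 0.29 on the log2 scale, and with 10-DE GIMAP4 and GIMAP7 rose by 0.36 each, calls that 5 alternatives each ended. The scalings tried moved the median of all genes by at most 0.04 on the log2 scale, less than any of these changes. Reads shared between these related genes were not examined.

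Among naive and memory T cell genes, IL7R, the interleukin-7 receptor gene, rose by 0.41 and 0.38 on the log2 scale with WT IL-10 and super-10, while the list as a whole (5 higher and 2 lower, and 3 higher and 3 lower, of 16) did not pass camera (adjusted p 0.174 and 0.333 with the preset correlation). Of the activation and costimulatory markers, which did not pass against PBS either (5 higher and 9 lower of 20 with WT IL-10, 4 and 8 with super-10, 1 and 2 with 10-DE; adjusted p 0.174, 0.507 and 0.826), TNFRSF9, the gene of 4-1BB, fell by 0.77, 0.60 and 0.29 on the log2 scale with WT IL-10, super-10 and 10-DE, and TNFRSF4, the gene of OX40, fell by 0.68, 0.31 and 0.43, while TNFRSF8 rose by 1.49, 1.16 and 0.37.

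Between super-10 and WT IL-10, 15 members of the cytokine and granule lists together were called: 9 of 24 cytokine and chemokine genes were higher and 1 lower with super-10, and 5 of 16 granule genes were lower. Neither list passed with the estimated correlation (adjusted p 0.0504 each). All 15 were still called in the same direction after the GC and length offsets. That argues only weakly against such trends, as the offsets kept 174 of all 177 calls of this comparison and raised the count to 352. With the offsets the log2 difference of GZMA went from -0.41 to -0.33 and that of SRGN from -0.27 to -0.19. That of IFNG went from 1.43 to 1.51. A smaller WT IL-10 response was argued against for IFNG, which stood at log2 1.32 (SE 0.0581) with super-10 against -0.10 (SE 0.0587) with WT IL-10, outside the range between PBS and WT IL-10. For the other 14 it stays open: 10 of them had a super-10 mean between the PBS and WT IL-10 means, while FGFBP2, GZMA, IL26 and SRGN lay below both (the FGFBP2 and IL26 calls between the proteins were lost under 6 and 10 alternatives), of which SRGN alone was called lower than PBS (log2 -0.18). Other doses and times were not measured.

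The response to 10-DE was smaller than that to WT IL-10, with a slope of 0.378. GC and length trends were argued against, though weakly: the slope was 0.385 with the offsets, but it weighs large changes most. The trends were small beside such changes, the largest being -0.20 on the log2 scale between the GC extremes, in 10-DE replicate 2. A single share for every gene was also argued against: of 764 genes called for super-10 against PBS, 37 departed at an adjusted p under 0.05 from the share of 0.418 fitted over them, and SOCS3 departed by -0.68 (adjusted p 7.27e-07), CCL17 by 0.51 and GZMB by -0.29. The bound first written, at most 5% departing, was met (4.84%), and the reading was amended after SOCS3 was seen, because adjusted departures should be near 0 if 1 share held for every gene. Of the 37, 6 were mitochondrial transcripts, whose share of counts was lower in the 10-DE than in the WT IL-10 libraries; with mitochondrial transcripts left out, 29 of 755 genes departed. Over all 14058 tested genes, chosen by no comparison, 17 departed, 2 of them mitochondrial, and SOCS3 was among them (adjusted p 1.34e-05). The STAT3 and cytokine feedback list departed downwards at an adjusted p of 1.51e-04 with the preset correlation but 0.35 with the estimated one, and the cholesterol and fatty acid list departed upwards at 0.0135 and 0.35, so whether either departs as a group stays open.

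For 10-DE against PBS, 40 genes were called with all samples and 359 without PBS replicate 1. GC and length trends may account for much of this: with the offsets the counts were 96 and 143, a ratio of 1.49, just under the bound of 1.5 written beforehand. Without PBS replicate 2 the count with offsets was 108, and without 10-DE replicate 1 or 2 it was 39 and 41. The offsets also lowered the common biological coefficient of variation from 5.12% to 3.80% and the median difference between the PBS samples from 0.105 to 0.0739 on the log2 scale. Leaving out a PBS sample takes the difference between the PBS samples out of the shared estimate of the spread. Counts then rose in the comparisons between proteins as well. The offsets narrow that same difference, so the ratio cannot separate GC and length trends from this effect on the spread. No biological explanation was tested, as both PBS samples carry the same labels.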
